A study of Homo sapiens with 19 samples.

How the data were processed

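RELA ChIP-seq was done in Detroit 562 cells after stimulation with TNFα, LPS, M tri-DAP, Pam2CSK4 or Poly I:C, with 2 biological duplicates for each stimulus per the series design text. Per the labels, 8 no-treatment RELA ChIP samples (1 for each of batches 1 to 8) and 1 input DNA sample completed the 19 samples, and the no-treatment cells had a change of medium. The duplicates lay in batches 1 and 3 for LPS, 2 and 4 for TNFα, 5 and 6 for Pam2CSK4, 5 and 7 for Poly I:C, and 8 and 7 for M tri-DAP, per the labels. Per the labels' protocols, cells were crosslinked with formaldehyde, chromatin was sonicated and precipitated with an anti-RELA antibody, and libraries were built on the beads.

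Per the series design text, peaks of the stimulated samples were called against input DNA together with the no-treatment RELA ChIP of the same batch. Per the submitters' processing notes, the build was hg19 and the tools included BWA, SAMtools 1.2 and bedtools, without the role of each. The peak caller and its threshold were not given in the sources used here. The deposited files hold 1 peak list per stimulus for both duplicates, with 3 columns (chromosome, start and end, in other units than counts or scores, namely base positions). The deposited values carry no normalization, score, height, p-value or read count. The peaks of each list were in order of width, and 59.5% (Pam2CSK4) to 71.2% (LPS) of widths were multiples of 50 bp. Start positions were read as counted from 0 and are given here counted from 1.

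Sequencing depth per sample, signal in the input and no-treatment samples and the spread between duplicates could not be derived from peak lists. Intervals given here therefore cover counting error over peaks only, peaks are not independent replicates, and each p describes these lists. Read alignments and signal tracks were not analysed here.

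Except where stated otherwise, the lists, comparisons, gene lists, naming rule, tests and alternatives were fixed before the data were examined. The McNemar tests between stimuli and the permutation of the stimulus over peaks of a single list were not in that plan. Nor were the start site tests of peaks held by a single list. Where a choice relied on a peak score, width took its place, as the naming rule foresaw for genes and regions. The alternatives that keep the upper part of each list or lists of equal length used width too, as did the comparison by sharing, a choice made once the files were seen to hold no score.

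Peaks of the 5 lists that overlapped by at least 1 bp were merged into regions, and each region was counted by the lists that held it. Random placement shifted each list by its own offset around every chromosome (1000 draws, 100 under the alternatives). Pairwise overlap was the share of the shorter list's peaks that overlapped a peak of the other list, with Benjamini-Hochberg adjustment over 10 pairs. A peak's width was ranked within its list, and peaks in 5 lists and in 1 list were compared by permutation of the difference in medians (100000 permutations, 10000 under the alternative, two-sided).

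Genes and transcription start sites came from GENCODE 44 mapped to hg19 (19748 protein-coding genes with 78530 distinct start sites), and bases from the hg19 reference. All 31 sequences that held peaks were found in the reference, and on 1 of them the last peak ended past its length. Overlaps used all sequences, and analyses of start sites, genes and bases used chromosomes 1 to 22 and X. Peaks within 1 kb of a start site were compared with the same peaks after 1 random shift by Fisher's exact test (two-sided), adjusted over 12 sets. Each centre was also placed at a start site (within 1 kb), in an exon, in an intron or between genes.

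The 16 gene lists were NF-kB feedback and signalling, chemokines, cytokines and growth factors, adhesion with matrix and coagulation, epithelial antimicrobial and acute phase, type I and III interferon response, survival and death receptors, antigen presentation, receptors and adaptors of the stimuli, AP-1 and immediate early, squamous epithelial, ribosomal proteins, and markers of hepatocytes, neurons, T and B cells, and macrophages. All 324 list entries were found in the annotation, DDX58 under its current symbol RIGI. The entries with a peak within 10 kb of a start site were compared with all other protein-coding genes by Fisher's exact test (one-sided), adjusted over lists and sets at a threshold of 0.05. Differences between stimuli in each list were tested by exact McNemar tests over genes.

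Genes were named by rule. In each list these were up to 4 genes with peaks under most stimuli, ranked by the median width percentile of their widest peak, and up to 4 genes with a peak under 1 stimulus only. Regions named were the 5 regions of all 5 lists with the highest median width percentile and the 3 widest peaks per stimulus that overlapped no other list. Genes named beyond this rule are said to be chosen after their values were seen. Values of some single genes are not reported here.

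Matches to GGGRNWYYCC (kB), GAAANNGAAA (ISRE), TGASTCA (AP-1), ACCGGAAGT (ETS) and CCASYAGRKGGC (CTCF) on either strand were counted in each peak and in a sequence of equal width 2 kb away that touched no peak. They were compared by Fisher's exact test (two-sided), adjusted over motifs and sets, with 95% Wald intervals of the odds ratio. Differences between the lists among peaks found in 1 list were tested by 10000 permutations of the stimulus over these peaks. Peaks are the units of that test, and it cannot compare stimuli across replicates.

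Alternatives were reciprocal overlap of 50%, centres within 200 bp, the peaks above width percentile 50 or 75, equal lists of 10893 peaks, each stimulus left out in turn, offsets of at most 1 Mb, and leaving out the 5% of 1 Mb bins with most peaks (130 of 2596 bins). Others were distances of 2.5 and 5 kb for start sites and 2 and 50 kb for genes, 1 gene per run of list genes within 100 kb, the looser kB consensus GGRRNNYYCC, the central 200 bp of peaks, and flanks 5 kb away. The ISRE with a pyrimidine between its repeats, and each consensus read backwards, were added after the data were seen.

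The overlap, enrichment and motif code was tested on simulated data. Of 2000 regions planted in all 5 lists, 1998 were found in all 5, and of 2500 peaks planted in 1 list, 2490 were found in 1. Of the 2000 shared regions, reciprocal overlap of 50% found 1545 in all 5 lists, and centres within 200 bp found 2000. Among 200 simulated lists of 18 genes, 99.5% were called when about 50% of their genes were given a peak, and 5.5% of lists left unchanged passed at an unadjusted p under 0.05. A planted motif share of 30% was recovered as 29.1% to 32.1%. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.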

Results

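RELA, the p65 subunit of the transcription factor NF-kB, was mapped by ChIP-seq in Detroit 562 cells, an established human pharyngeal carcinoma line, after stimulation with 5 microbial or inflammatory agents. LPS, a bacterial outer membrane lipid sensed through TLR4, was given at 1 µg/mL for 80 minutes. TNFα, an inflammatory cytokine, was given at 10 ng/mL for 50 minutes, and Pam2CSK4, a synthetic lipopeptide ligand of TLR2, at 1 µg/mL for 60 minutes. The others were Poly I:C, a synthetic double-stranded RNA (10 µg/mL for 90 minutes), and M tri-DAP, a peptidoglycan fragment sensed by NOD receptors (15 µg/mL for 90 minutes). The series held 19 samples, namely 2 biological duplicates per stimulus, 8 no-treatment RELA ChIP samples in batches 1 to 8, and 1 input DNA sample. LPS and TNFα samples lay in batches 1 to 4 and the samples of the other agents in batches 5 to 8, so that batch set and stimulus could not be told apart. Each stimulus had 1 peak list for its duplicates, with positions alone. Sequencing depth, peak heights and the spread between duplicates were therefore unknown, and the stimulation times differed between agents.

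RELA peaks numbered 15155 after TNFα, 13696 after Pam2CSK4, 12571 after Poly I:C, 12198 after LPS and 10893 after M tri-DAP. Median peak width was lowest after LPS, at 650 bp (interquartile range 501 to 871), and highest after Poly I:C, at 879 bp (700 to 1199). It was 770 bp (629 to 1000) after TNFα, 800 bp (650 to 1095) after Pam2CSK4 and 812 bp (650 to 1088) after M tri-DAP. The lists covered between 9.42 Mb (LPS) and 13.96 Mb (TNFα) of the genome. With the no-treatment ChIP already used as background in peak calling, per the series design text, no untreated peak list served as a separate comparison.

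The question of which RELA sites the 5 stimuli have in common was asked of the merged peaks. RELA occupied 6536 regions after every one of the 5 stimuli, 31.4% of the 20804 distinct regions. Ranked by the median over the lists of their width percentile, the first of these was at EFNA1, which encodes an ephrin ligand (hg19, chromosome 1, 155096214 to 155102929, centre within 1 kb of a transcription start site). Next came the neutrophil chemokine gene CXCL8 (chromosome 4, 74605029 to 74611578, centre in an exon). Another was at the chemokine gene CXCL1 (chromosome 4, 74733536 to 74739066, centre in an exon). The others were at BIRC2, an inhibitor of apoptosis (chromosome 11, 102214136 to 102219935, centre within 1 kb of a start site), and at KYNU, a kynurenine pathway enzyme (chromosome 2, 143629943 to 143636186, intergenic centre, edge at the start site). Regions in 4, 3 and 2 lists numbered 2644 (12.7%), 2614 (12.6%) and 3331 (16.0%). Lists placed at random along the chromosomes gave a mean of 0.003 and at most 1 region in all 5 lists (one-sided permutation p = 0.001, the smallest 1000 draws can give). The p describes these lists and not replicates, and the input library common to all 5 peak calls could not be separated from shared binding. Random placement also took no account of which parts of the genome can hold peaks. Lists that merely lie in the same parts of the genome would pass it too, so p does not measure binding driven by the stimuli.

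**Figure D1:**
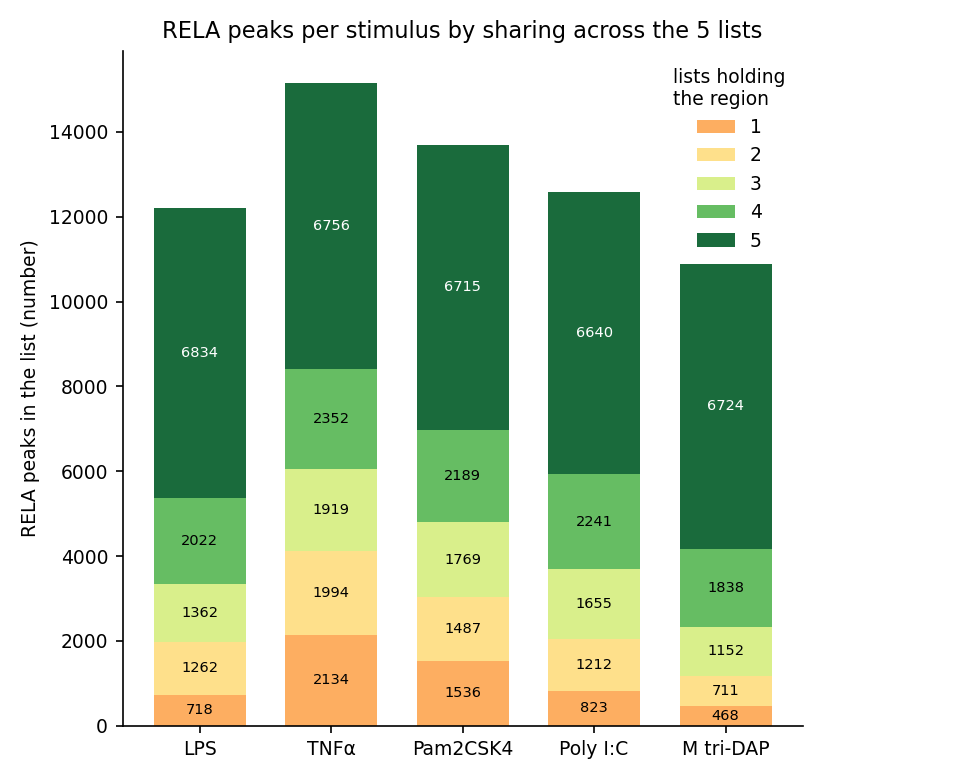
RELA peaks per stimulus (bars, number of peaks), divided by the number of lists, 1 to 5, that hold the peak's region. Peaks in regions held by all 5 lists form the largest part of each bar, from 6640 peaks after Poly I:C to 6834 after LPS.

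The gene of an inhibitor that switches NF-kB off again lay among the widest peaks. At TNFAIP3, which encodes the ubiquitin-editing inhibitor A20 (chromosome 6, 138188351 to 138204451, plus strand), the widest peak ran from 138187097 to 138195646 (8550 bp) after TNFα and from 138186700 to 138195799 (9100 bp) after Poly I:C. After the other stimuli separate peaks lay over about the same stretch. They were 2934 and 3750 bp wide after LPS, 2450 and 2050 bp after Pam2CSK4, and 3162 and 4712 bp after M tri-DAP. At CXCL8 (chromosome 4, 74606236 to 74609433, plus strand) the peak covered the whole gene under all 5 stimuli, with widths from 5053 bp (M tri-DAP) to 6550 bp (Poly I:C). At ICAM1, the leukocyte adhesion molecule of epithelium and endothelium (chromosome 19, 10381769 to 10397291, plus strand), a peak over the start site was 2500 bp wide after LPS and 2800 to 3000 bp wide after the others. IFNL1, a type III interferon gene (chromosome 19, 39787047 to 39789313, plus strand), had a peak over its start site after Poly I:C alone, at 39786648 to 39787297 (650 bp, width percentile 17.3 of that list). A gene said to have a peak under all 5 stimuli need not have it at the same position in each.

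**Figure D2:**
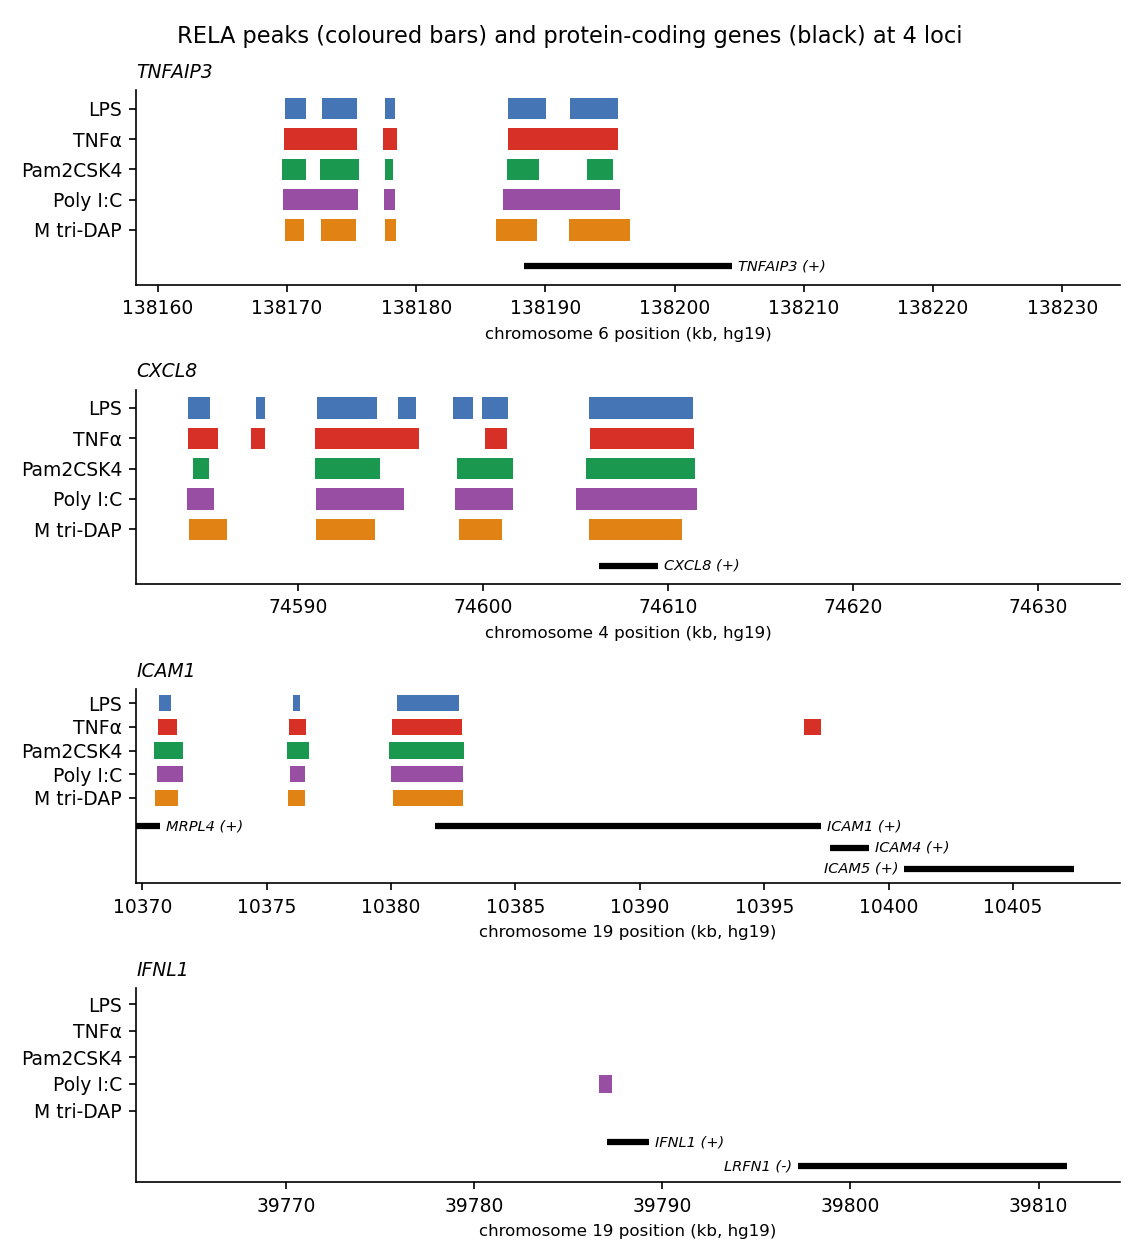
Peaks of the 5 lists (coloured bars) and protein-coding genes (black bars, strand in brackets) around TNFAIP3, CXCL8, ICAM1 and IFNL1, by position in kb on hg19. TNFAIP3, CXCL8 and ICAM1 carry peaks under all 5 stimuli, and IFNL1 after Poly I:C alone.

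RELA regions found in 1 list numbered 5679 (27.3% of regions). The widest after TNFα lay in an intron of CRTAC1 (chromosome 10, 99647133 to 99649932), at the start site of the membrane-binding protein gene ANXA2 (chromosome 15, 60690018 to 60692617). Another lay 71496 bp from the start site of the proto-oncogene MYC (chromosome 8, 128673585 to 128676184, intergenic). After Pam2CSK4 they lay at the start sites of the autophagy gene UVRAG (chromosome 11, 75523736 to 75527237) and of PPP1R13L, which encodes the p53 inhibitor iASPP (chromosome 19, 45906623 to 45910018). Another lay 46980 bp from BIRC3 (chromosome 11, 102138288 to 102141235, intergenic). Poly I:C had them in an intron of ZPLD1 (chromosome 3, 101897554 to 101900939), near TARBP1 (chromosome 1, 234634580 to 234637479, intergenic) and at the start site of RND3 (chromosome 2, 151341922 to 151344692). After LPS the widest were intergenic near TBC1D4 (chromosome 13, 75754870 to 75756469) and NSUN7 (chromosome 4, 40723668 to 40725117) and intronic in SULT1B1 (chromosome 4, 70615668 to 70617217). After M tri-DAP they lay at the start site of WDR81 (chromosome 17, 1617952 to 1621151) and between genes nearest to MAP2 (chromosome 2, 209847475 to 209849824) and CCDC34 (chromosome 11, 27239546 to 27241732).

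Such peaks made up 14.1% of the TNFα list (2134 peaks, 95% Wilson interval 13.5% to 14.6%) and 11.2% after Pam2CSK4 (1536, 10.7% to 11.8%). They made up 6.55% after Poly I:C (823, 6.13% to 6.99%), 5.89% after LPS (718, 5.48% to 6.32%) and 4.30% after M tri-DAP (468, 3.93% to 4.69%). No test compared these shares, because each stimulus had 1 list. With lists of equal length, the number fell to 985 for TNFα and rose to 949 for M tri-DAP. With sharing defined by centres within 200 bp it was 1496 for Poly I:C, 1191 for LPS and 874 for M tri-DAP.

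Peaks shared by all 5 stimuli were wider within their list than peaks found in it alone. After TNFα the median width percentile was 68.3 for shared peaks and 20.9 for peaks of that list alone, and after LPS it was 65.2 and 17.4. The pairs were 65.6 and 21.3 after Pam2CSK4, 63.3 and 24.3 after Poly I:C, and 60.5 and 20.8 after M tri-DAP (two-sided permutation tests, p = 1e-05 for each, the smallest 100000 permutations can give). A wide peak also has more room to overlap another. With sharing defined by centres within 200 bp, the gap of 39.0 points after Poly I:C was 3.73 points, that of 39.7 after M tri-DAP was 6.82, and that of 47.8 after LPS was 31.9 (p = 0.0001, permutation tests, the smallest 10000 permutations can give).

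LPS and TNFα shared the largest part of a shorter list, with 85.0% of LPS peaks overlapping a TNFα peak (95% Wilson interval 84.3% to 85.6%). The smallest part was 74.8% (74.1% to 75.5%), for Pam2CSK4 peaks against the TNFα list. Random placement gave means of 0.729% to 1.04% over the 10 pairs (one-sided permutation p = 0.001 for each pair, the smallest 1000 draws can give, adjusted p = 0.001). Here too, placement took no account of which parts of the genome can hold peaks. As a share of the regions in either full list, overlap was highest for Pam2CSK4 and Poly I:C (62.0%), LPS and TNFα (60.4%), and Poly I:C and M tri-DAP (60.0%), and lowest for TNFα and M tri-DAP (53.9%). This order depended on list length. With equal lists the share was highest for LPS and TNFα (61.4%), lowest for LPS and Pam2CSK4 (53.7%), and 57.4% for TNFα and M tri-DAP. Pam2CSK4 and Poly I:C shared batch 5, and Poly I:C and M tri-DAP shared batch 7, with the no-treatment library of that batch.

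RELA peaks lay at transcription start sites more often than the same peaks shifted at random, with the highest shares after Pam2CSK4 and M tri-DAP. Within 1 kb of the start site of a protein-coding gene lay 13.9% of Pam2CSK4 peaks (95% Wilson interval 13.3% to 14.5%), 13.6% of M tri-DAP peaks (12.9% to 14.2%). The shares were 12.5% of Poly I:C peaks (11.96% to 13.1%), 10.1% of TNFα peaks (9.64% to 10.6%) and 8.43% of LPS peaks (7.95% to 8.94%). Shifted peaks gave 3.04% to 3.34%, and the odds ratios ran from 2.94 for LPS to 4.93 for Pam2CSK4 (Fisher's exact test, two-sided, adjusted p from 1.4e-235 to 1.9e-75). The shift likewise ignored which parts of the genome can hold peaks. Most other peaks had intergenic centres (47.4% to 50.3% over the lists) or intronic centres (38.2% to 40.8%), and exons held 1.74% to 1.93%. Regions in all 5 lists lay near a start site in 11.0% of cases (odds ratio 3.44) and regions in 1 list in 14.9% (odds ratio 5.86). The latter share depended on the list, at 5.61% for LPS and 6.90% for TNFα, and 23.4% for Pam2CSK4, 17.4% for Poly I:C and 32.5% for M tri-DAP.

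The NF-kB feedback and signalling genes carried RELA peaks within 10 kb of a start site almost throughout. Of 27 such genes, 24 had a peak after LPS, 26 after TNFα, 25 after Pam2CSK4, 23 after Poly I:C and 25 after M tri-DAP, and 21 had one under all 5 stimuli. By median width percentile the first was TNIP1, a ubiquitin-binding inhibitor of NF-kB (chromosome 5, minus strand), with a peak of 9600 bp at 150459179 to 150468778 after Poly I:C. It was followed by TNFAIP3, BIRC2 and TNFAIP2, a TNF-induced gene whose peak of 4849 bp after Pam2CSK4 lay at 103574551 to 103579399 on chromosome 14. TRAF3, an adaptor that restrains non-canonical NF-kB signalling, had a peak after TNFα alone (chromosome 14, 103245906 to 103246583). Against all 19748 protein-coding genes, of which 13.1% (LPS) to 18.9% (Pam2CSK4) had a peak, the odds ratios were 29.3 (Poly I:C) to 125 (TNFα), with adjusted p from 1.5e-17 to 9.8e-14 (Fisher's exact test, one-sided).

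Inflammatory mediator genes carried peaks under every stimulus as well. Of 15 chemokine genes, 14 had a peak after LPS, TNFα, Pam2CSK4 and Poly I:C and 13 after M tri-DAP, including CXCL1, CXCL2, CXCL3 and CXCL8, which recruit neutrophils (adjusted p from 5.1e-11 to 1.1e-08). Of 24 cytokine and growth factor genes, 19 to 21 had a peak (adjusted p from 6.3e-15 to 1.2e-10). Among these, LTA, LTB and TNF shared a peak on chromosome 6, 5150 bp wide at 31545650 to 31550799 after Poly I:C and 1234 bp wide at 31545757 to 31546990 after LPS. LIF, an interleukin 6 family cytokine, had peaks of 3350 to 3600 bp on chromosome 22. Of 18 adhesion, matrix and coagulation genes, 13 to 15 had a peak (adjusted p from 4.6e-09 to 4.2e-07), among them the laminin gene LAMB3, with a peak of 7479 bp at 209824235 to 209831713 on chromosome 1 after TNFα. ICAM1, the hyaluronan receptor gene CD44 and PTX3, which encodes a soluble pattern recognition molecule, also had peaks under all 5 stimuli. ICAM4 had a peak after TNFα alone (chromosome 19, 10396590 to 10397286, 697 bp). Of 16 survival and death receptor genes, 11 to 13 had a peak (adjusted p from 1.1e-07 to 7.4e-06). BIRC3, CFLAR, IER3 and GADD45A had one under all 5 stimuli, and the apoptosis inhibitor BCL2 after Pam2CSK4 alone (chromosome 18, 60828987 to 60829486). The BCL2 peak was among the narrowest of that list (width percentile 6.12). It lay over a start site well inside the gene (60790579 to 60987361, minus strand).

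Of 22 antimicrobial and acute phase genes of the epithelium, 14 had a peak after Pam2CSK4 and after Poly I:C, 13 after M tri-DAP, 12 after LPS and 9 after TNFα. The complement gene C3, the prostaglandin synthase gene PTGS2, the mitochondrial superoxide dismutase gene SOD2 and LCN2, which binds bacterial siderophores, had peaks under all 5 stimuli. NOS2, PI3, S100A9 and SLPI, chosen after their values were seen, lacked a peak after TNFα alone. By Fisher's exact test the adjusted p was 2.8e-06 to 1.2e-05 for the other stimuli and 0.014 for TNFα, whose call ended at a distance of 50 kb (adjusted p = 0.11, range over the alternatives 0.0013 to 0.11).

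Of 28 genes of the type I and III interferon response, 14 had a peak after Poly I:C (odds ratio 5.08), 12 after Pam2CSK4, 11 after M tri-DAP, 10 after TNFα and 9 after LPS. The transcription factor gene IRF1 (chromosome 5, minus strand) had a peak of 3000 to 3351 bp under all 5 stimuli, and the interferon-induced genes ISG15, IFIT3 and ZC3HAV1 also had peaks under all of them. IFNL1 and DHX58, which encodes an RNA sensor of the RIG-I family (chromosome 17, peak at 40263961 to 40264460, 500 bp), had a peak after Poly I:C alone. The DHX58 peak was among the narrowest of that list (width percentile 2.90). By Fisher's exact test the adjusted p was 9.7e-05 for Poly I:C, 0.0041 for M tri-DAP, 0.006 for Pam2CSK4, 0.014 for LPS and 0.027 for TNFα. At 2 kb the calls for LPS and TNFα ended (exact test, adjusted p = 0.054 and 0.071). At 50 kb the call for Poly I:C stayed (exact test, adjusted p = 0.0093, range over the alternatives 7.3e-05 to 0.0093). It ended for M tri-DAP (0.074, range 0.0027 to 0.074), Pam2CSK4 (0.21, range 0.0011 to 0.21), LPS (0.16, range 0.0055 to 0.16) and TNFα (0.50, range 0.0037 to 0.50).

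Antigen presentation genes had a peak in 7 of 18 cases after LPS, 12 of 18 after TNFα, Pam2CSK4 and Poly I:C, and 14 of 18 after M tri-DAP. The peptide loading gene TAPBP and the class I light chain gene B2M had peaks under all 5 stimuli. TAP1, a peptide transporter subunit, and the immunoproteasome gene PSMB9 shared a peak over their start sites after M tri-DAP (chromosome 6, 32820412 to 32822311, 1900 bp) and after TNFα, Pam2CSK4 and Poly I:C, while their widest peak after LPS was at 32828941 to 32829390 (450 bp). PSME1 and PSME2, which encode the proteasome activator PA28, had a peak after M tri-DAP alone (chromosome 14, 24615301 to 24616650, 1350 bp). CD40, HLA-B, NLRC5 and PSMB8, chosen after their values were seen, were among the genes that lacked a peak after LPS alone. By Fisher's exact test the adjusted p was 0.011 for LPS and 3.2e-08 to 2.9e-05 for the others. The call for LPS ended when peaks above width percentile 50 were used (exact test, adjusted p = 0.21, range over the alternatives 0.0060 to 0.21).

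**Figure D3:**
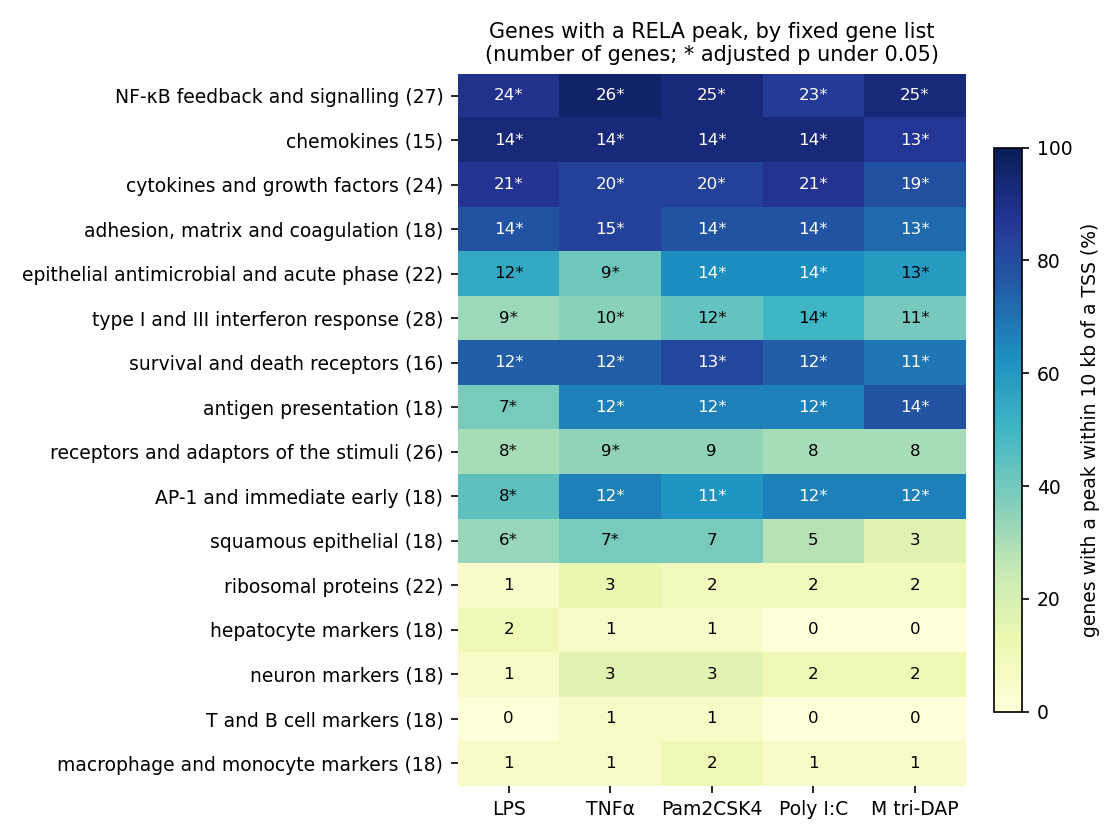
Genes of each fixed list (list size in brackets) with a RELA peak within 10 kb of a transcription start site, by stimulus, with the colour giving their percent, the figure in each cell their number and an asterisk an adjusted p under 0.05. NF-kB feedback genes range from 85.2% to 96.3%, while ribosomal protein genes range from 4.55% to 13.6%, beside 13.1% to 18.9% of all genes.

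AP-1 and immediate early genes had a peak in 8 of 18 cases after LPS, 11 after Pam2CSK4 and 12 after TNFα, Poly I:C and M tri-DAP (adjusted p from 4.3e-06 to 0.0023). KLF6, KLF10, the AP-1 subunit gene JUNB and ZFP36, which destabilises cytokine mRNAs, had peaks under all 5 stimuli, and EGR3 after TNFα alone (chromosome 8, 22560885 to 22561684). Of 26 receptor and adaptor genes of the stimuli themselves, 8 or 9 had a peak, including IRAK2, TLR2, RIPK2 and TBK1 under all 5 stimuli. NOD2 had one after Poly I:C alone (chromosome 16, 50730818 to 50732267) and TNFRSF1A, the TNF receptor, after TNFα alone (chromosome 12, 6441695 to 6442144). The TNFRSF1A peak was among the narrowest of its list (width percentile 3.11), while that of NOD2 was at percentile 84.2. For this list the adjusted p was 0.027 for LPS, 0.042 for TNFα, 0.061 for M tri-DAP, 0.067 for Pam2CSK4 and 0.08 for Poly I:C. Its calls for LPS (range 0.015 to 0.099) and TNFα (range 0.017 to 0.18) ended at 50 kb and above width percentile 50, and for TNFα also with equal lists. Those for M tri-DAP, Pam2CSK4 and Poly I:C passed under 1 or more alternatives. The call for regions in all 5 lists (6 genes, exact test, adjusted p = 0.038) ended with equal lists (0.071, the highest over the alternatives, which went down to 0.032).

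Squamous epithelial genes had a peak in 6 of 18 cases after LPS, 7 after TNFα and Pam2CSK4, 5 after Poly I:C and 3 after M tri-DAP. KRT15 and SFN had peaks under all 5 stimuli, SPRR1B under 4, and the basal keratin gene KRT5 after LPS and TNFα (chromosome 12, 52914235 to 52916994 after TNFα). TP63, the master regulator of squamous identity, had a peak over its start site after Poly I:C alone (chromosome 3, 189347740 to 189349303, 1564 bp), and IVL after TNFα alone (chromosome 1, 152878614 to 152879163). Their width percentiles were 86.8 for TP63 and 13.3 for IVL. The adjusted p was 0.039 for LPS, 0.041 for TNFα, 0.061 for Pam2CSK4, 0.24 for Poly I:C and 0.79 for M tri-DAP. The call for LPS (range over the alternatives 0.00033 to 1.0) ended at 2 kb, above width percentile 50, with equal lists and with 1 gene per run, and that for TNFα (range 1.1e-05 to 0.62) under the last 3 of these. At 50 kb Pam2CSK4, Poly I:C and M tri-DAP passed with adjusted p of 0.00012, 0.0073 and 0.00013 by Fisher's exact test. Neighbouring genes of the list can share a peak at that distance and were counted singly there, so these p can overstate the enrichment.

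Control lists did not pass the test. Ribosomal protein genes had a peak in 1 to 3 of 22 cases per stimulus, among them RPL3 under 3 stimuli, RPS18 and RPL27 under 2, RPL4 after M tri-DAP, RPL18 after TNFα and RPS14 after Poly I:C. Hepatocyte markers had 0 to 2 of 18 (CYP2E1 under 3 stimuli, FGB after LPS). Neuron markers had 1 to 3 of 18 (MAP2 under 5, SYT1 under 4, RBFOX3 after Pam2CSK4, SYN1 after TNFα). T and B cell markers had 0 or 1 of 18 (IL2RA under 2) and macrophage markers 1 or 2 of 18 (ITGAM under 5, AIF1 after Pam2CSK4). The smallest adjusted p among these 5 lists was 0.89 over the stimuli and 0.7 for regions in all 5 lists. At regions in all 5 lists, 10 of the 16 lists passed, with 22 of 27 NF-kB feedback genes (odds ratio 46.4) and 1 of 18 squamous genes (exact test, adjusted p = 1.0). The interferon and antigen presentation calls there (exact tests, adjusted p = 0.00094 and 0.0011) ended above width percentile 50 (0.54 and 0.30, the highest over the alternatives, which went down to 0.0011 and 0.0060).

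Differences between stimuli in these lists could hardly be tested. Of 160 exact McNemar tests, each of 1 list between a pair of stimuli, 0 passed after adjustment (smallest adjusted p = 1.0). Differing genes were most numerous for squamous genes in TNFα against Poly I:C, with 5 and 3. So few leave little room to pass adjustment, so the outcome does not show that the stimuli are alike. Genes that share a peak, such as PSME1 and PSME2, were counted singly. Antigen presentation genes in LPS against M tri-DAP gave the 1 unadjusted p under 0.05, with 0 genes in LPS alone and 7 in M tri-DAP alone (exact p = 0.0156). For interferon genes in LPS against Poly I:C the numbers were 0 and 5 (exact p = 0.0625), the smallest p that 5 differing genes can give.

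The kB site, the DNA element that NF-kB dimers bind (consensus GGGRNWYYCC), was present in 27.5% of LPS peaks, 30.8% of TNFα peaks, 36.0% of Pam2CSK4 peaks, 36.2% of Poly I:C peaks and 35.9% of M tri-DAP peaks. Sequences of equal width 2 kb away held it in 6.04% to 8.48% of cases, and the odds ratios ran from 5.06 for TNFα (95% Wald interval 4.72 to 5.41) to 6.33 for Pam2CSK4 (5.90 to 6.80). The AP-1 site (TGASTCA), bound by FOS and JUN proteins, was present in 47.3% of Poly I:C peaks to 49.0% of TNFα peaks, with odds ratios from 4.89 to 7.39. These shares depend on peak width. Within the central 200 bp the kB site was present in 15.7% of LPS, 16.0% of TNFα, 19.1% of Pam2CSK4, 18.4% of Poly I:C and 18.1% of M tri-DAP peaks. The AP-1 site was present there in 27.1% of LPS, 25.4% of TNFα, 23.3% of M tri-DAP, 22.9% of Pam2CSK4 and 20.7% of Poly I:C peaks. The interferon-stimulated response element (ISRE, GAAANNGAAA) was present in 19.5% of Poly I:C peaks against 16.3% of flanks (odds ratio 1.25, 95% Wald interval 1.17 to 1.33, adjusted p = 1.3e-10 by Fisher's exact test). For the other stimuli it lay at 13.5% to 15.9% against 12.4% to 14.9%, with adjusted p from 0.0015 to 0.077 by exact tests. Within the central 200 bp the shares of LPS, TNFα and Pam2CSK4 no longer passed (exact tests, adjusted p = 0.46, 0.13 and 0.77). ETS sites (ACCGGAAGT) were present in 0.20% (LPS) to 0.47% (M tri-DAP) of peaks, with adjusted p from 1.8e-05 to 0.013. CTCF sites (CCASYAGRKGGC) were present in 0.47% (LPS, adjusted exact p = 0.068) to 1.0% (Poly I:C, adjusted p = 5.5e-08). Within the central 200 bp the ETS calls for LPS and TNFα ended (adjusted exact p = 0.3 and 0.11), as did the CTCF calls for TNFα, Poly I:C and M tri-DAP (0.59, 0.15 and 0.11).

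Regions in all 5 lists held a kB site in 41.7% of cases (odds ratio 5.52) and regions in 1 list in 23.3% (odds ratio 5.18), and AP-1 sites in 56.6% and 38.0%. The ISRE was present in 23.3% of regions in all 5 lists against 21.6% of flanks (adjusted exact p = 0.032), a direction that turned within the central 200 bp, at 3.55% against 3.62%. It was present in 12.6% of regions in 1 list against 11.0% (adjusted exact p = 0.022, and 0.11 within the central 200 bp). Because shared regions were wider, the central 200 bp of peaks were compared as well. After LPS, kB sites lay in the centre of 20.7% of peaks shared by all 5 stimuli (95% Wilson interval 19.8% to 21.7%) and 4.21% of peaks of that list alone (2.96% to 5.94%). The shares were 18.8% (17.9% to 19.7%) and 11.1% (9.86% to 12.5%) after TNFα, and 19.0% and 18.9% after Pam2CSK4, 17.9% and 17.4% after Poly I:C, and 18.8% and 15.6% after M tri-DAP. For AP-1 the order turned in the central 200 bp of regions, at 20.9% in all 5 lists and 22.7% in 1 list. Central AP-1 shares of shared peaks and peaks of 1 list were 25.6% and 29.6% after LPS, and 23.7% and 27.6% after TNFα. They were 22.6% and 20.4% after Pam2CSK4, 22.5% and 13.6% after Poly I:C, and 24.3% and 14.1% after M tri-DAP.

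Peaks of the Poly I:C list alone held an ISRE in 25.5% of cases against 12.1% of their flanks (odds ratio 2.49, 95% Wald interval 1.92 to 3.24, adjusted p = 1.3e-11 by Fisher's exact test), while peaks of the other single lists held one in 8.80% (M tri-DAP) to 10.8% (TNFα). The kB site was present in 7.18% of peaks of the LPS list alone against 3.52% of flanks (odds ratio 2.12, 1.30 to 3.46, adjusted exact p = 0.003). It was present in 18.02% after TNFα, 32.4% after Pam2CSK4, 29.9% after Poly I:C and 30.3% after M tri-DAP. For LPS the call ended with flanks 5 kb away (adjusted exact p = 0.12) and above width percentile 50 (0.33, range over the alternatives 0.00091 to 0.33). Shuffling the stimulus over peaks found in 1 list gave p = 0.0001 for the differences in ISRE and in kB (permutation tests, adjusted p = 0.0002, the smallest 10000 permutations can give). With peaks as units and 1 list per stimulus, p describes these lists and not replicates of a stimulus.

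**Figure D4:**
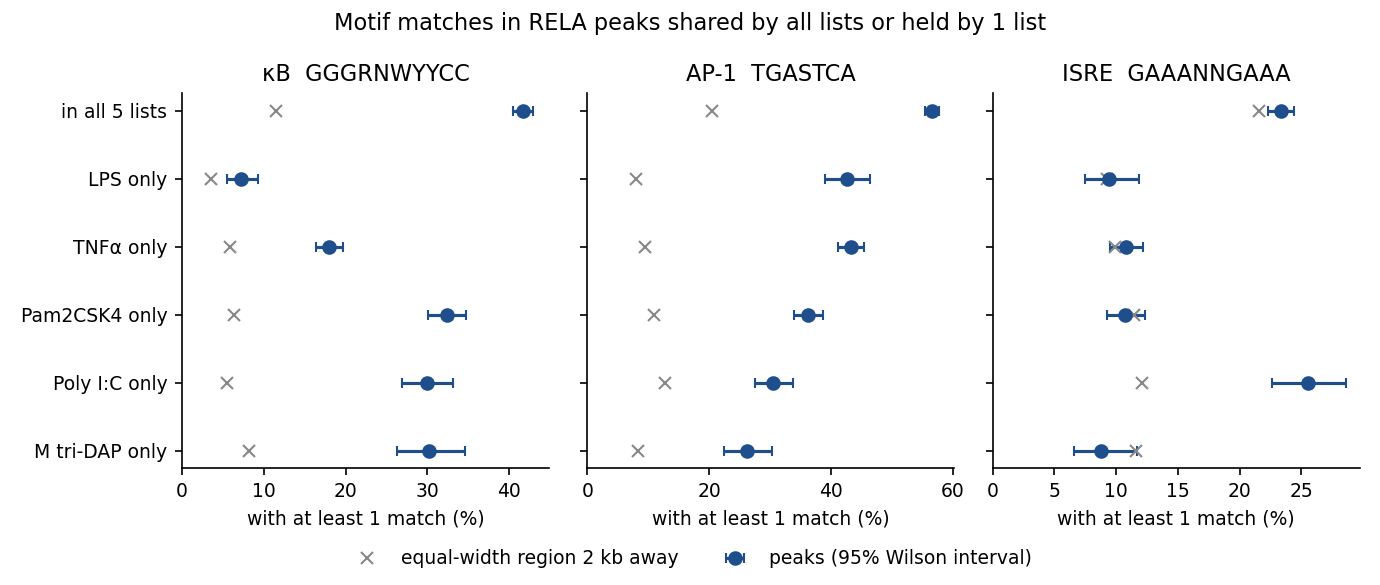
Percent of peaks with a match to the kB, AP-1 and ISRE consensus in regions held by all 5 lists and in peaks of a single list (points, with 95% Wilson intervals), beside sequences of equal width 2 kb away (crosses). The ISRE share of peaks of the Poly I:C list alone (25.5%) stands above that of the other single lists (8.80% to 10.8%). Shares are over whole regions or peaks, and regions held by all 5 lists are wider.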

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

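The tests of peak width, of base composition, of the batch sets, of shared no-treatment libraries and of list length were chosen after the results were seen, as was the count on the contig GL000199. The permutation of the stimulus over peaks was not among the tests fixed beforehand.

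Peaks found in 1 list differed between the lists in location and in motif content (permutation of the stimulus over these peaks, p = 0.0001 and adjusted p = 0.0002 for each of the 4 shares, the smallest 10000 permutations can give). Each stimulus had 1 list and peaks were the units shuffled, so p describes these lists and not replicates of a stimulus. Within 1 kb of a start site lay 5.61% of LPS-only peaks, 6.90% of TNFα-only peaks, 23.4% of Pam2CSK4-only peaks, 17.4% of Poly I:C-only peaks and 32.5% of M tri-DAP-only peaks. An AP-1 site was present in 42.7% of LPS-only, 43.3% of TNFα-only, 36.2% of Pam2CSK4-only, 30.5% of Poly I:C-only and 26.2% of M tri-DAP-only peaks. In both shares the stimuli of batches 1 to 4 stood on the opposite side from those of batches 5 to 8.

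An ISRE was present in 25.5% of Poly I:C-only peaks, against 9.44% of LPS-only, 10.8% of TNFα-only, 10.7% of Pam2CSK4-only and 8.80% of M tri-DAP-only peaks, an odds ratio of 2.93 against the other lists together (95% Wald interval 2.44 to 3.52). Wider peaks holding more matches were argued against by the central 200 bp, where the odds ratio was 3.58 (2.68 to 4.77), and purine tracts by matches with a pyrimidine between the repeats, where it was 3.33 (2.64 to 4.18). The consensus read backwards gave 1.87 (1.52 to 2.30), below the interval of the ISRE itself. Base composition was therefore not the whole cause, although a part of the difference may come from it. The same bases can match both patterns at neighbouring positions, so the odds ratio of 1.87 does not measure base composition alone. With an ISRE, 4 of 209 Poly I:C-only peaks lay within 50 kb of an interferon list gene, and without one 2 of 613 did (odds ratio 5.96, 1.08 to 32.8, Fisher's exact p = 0.039), which is in line with a hypothesis of RELA at interferon response sites but covers few peaks. The stimulus itself and the samples of batches 5 and 7, which Poly I:C shared with Pam2CSK4 and M tri-DAP, stay open.

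A kB site was present in 7.18% of LPS-only and 18.02% of TNFα-only peaks, against 32.4% of Pam2CSK4-only, 29.9% of Poly I:C-only and 30.3% of M tri-DAP-only peaks. In the central 200 bp it was present in 17.9% of the latter 3 sets together and 9.39% of the former (odds ratio 2.11, 95% Wald interval 1.80 to 2.47). Narrow peaks as the whole cause were argued against by peaks above width percentile 50, where the odds ratio was 1.95 (1.10 to 3.48), with shares of 7.07% and 3.75%. Nearness to the calling limit could not be tested, since the lists hold no score and a wide peak may still be weak. The odds ratio of 1.95 leaned on LPS (0 of 85 peaks), and against TNFα alone (17 of 368 peaks, 4.62%, near the 5.32% of Poly I:C) it was 1.57 (0.88 to 2.80). The fixed window held fewer matches in wider than in narrower peaks of every list, so whole peaks were compared as well. Over whole peaks above percentile 50 the site was present in 35.5% of the latter 3 sets, 20.1% of TNFα-only peaks (odds ratio 2.19, 1.61 to 2.97) and 8.24% of LPS-only peaks (6.14, 2.78 to 13.5). Median widths there were 850 bp for LPS, 946.5 bp for TNFα and 1000 to 1086 bp for the others, which gave the others more room for a match. More peaks at start sites were argued against by peaks over 1 kb from one, where the odds ratio was 2.37 (2.00 to 2.80).

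The kB consensus read backwards followed a similar order, at 5.21% of LPS-only, 9.60% of TNFα-only, 12.4% of Pam2CSK4-only, 10.5% of Poly I:C-only and 14.6% of M tri-DAP-only peaks. Its odds ratio of 1.495 (1.26 to 1.78) lay below that of kB itself over whole peaks (2.51, 2.21 to 2.86), so base composition was not the whole cause, although a part of the difference may come from it. Because 0 stimuli had duplicates in both batch sets, batches 1 to 4 against 5 to 8 cannot be told apart from the stimuli.

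Peak lists overlapped more within the batch sets than between them, with a mean Jaccard index of 59.5% within and 56.3% between for lists of equal length. The order did not hold pair by pair, since Pam2CSK4 and M tri-DAP, within batches 5 to 8, had an index of 57.1%, below 3 of the 6 pairs between the sets. List length as the whole cause was argued against by the gap of 3.23 points that equal lists kept. LPS and TNFα shared no batch, so by design a shared no-treatment library cannot be the cause for that pair. Their index was 61.4%, against at most 58.2% between the sets. Within batches 5 to 8 a shared no-treatment library stays open as a cause. The 2 pairs there that shared a batch (60.5% and 58.9%) lay above every pair between the sets, and the pair that did not (57.1%) lay among them. Of the 10 splits of the 5 stimuli into 2 and 3, 1 gave a gap as large, the real one, and the highest other gap was 3.04 points, for Pam2CSK4 and Poly I:C, which shared batch 5, against the rest. With 10 splits no share under 0.05 can be reached. Batches 1 to 4 against 5 to 8 cannot be told apart from a likeness of the stimuli themselves.

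The unplaced chromosome 9 contig GL000199 (169.874 kb), which entered no comparison of genes or motifs, held 15 LPS peaks, 13 TNFα peaks, 10 Pam2CSK4 peaks, 3 Poly I:C peaks and 10 M tri-DAP peaks. These were 21.99, 15.3, 13.1, 4.27 and 16.4 times the peak density of the whole genome.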

How the results depend on the processing

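The ISRE with a pyrimidine between its repeats, the consensus read backwards, and width as the measure for the upper part of each list and for equal lists were chosen after the data were seen. Of 793 recomputed values, 725 kept their call or stayed within their limit (23 of these changed direction with neither value past the threshold), 37 no longer passed, 9 newly passed, 20 counts moved and 2 reversed. Regions in all 5 lists numbered 5165 with centres within 200 bp, 5567 with equal lists and 5858 with reciprocal overlap. With 1 stimulus left out, regions in the remaining 4 lists numbered 6848 (without TNFα) to 7358 (without M tri-DAP). Pairwise overlap ranged from 62.95% to 85.0%, past random placement under every alternative run. Start site shares stayed above shifted peaks at 1, 2.5 and 5 kb, between 8.43% and 22.5%. The kB shares of the 5 lists and of regions in all 5 lists passed in every alternative run.

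By construction, width percentiles 50 and 75 left 5985 and 3054 peaks for LPS, 7575 and 3776 for TNFα, 6787 and 3426 for Pam2CSK4, 6281 and 3144 for Poly I:C, and 5446 and 2723 for M tri-DAP. Above percentile 50, regions in all 5 lists numbered 2883 and regions in 1 list 3577, squamous genes with an LPS peak fell to 1, below the background, and the kB share of LPS-only peaks was 8.24%, no longer past the threshold with fewer peaks. In the central 200 bp, which hold fewer matches by construction, the ISRE share of regions in all 5 lists reversed against flanks, at 3.55%. There the ISRE no longer passed for LPS (3.63%), TNFα (3.57%), Pam2CSK4 (3.46%) and regions in 1 list (3.80%), nor did ETS for LPS (0.0833%) and TNFα (0.107%), nor CTCF for TNFα (0.154%), Poly I:C (0.210%) and M tri-DAP (0.243%). With flanks 5 kb away, kB no longer passed for LPS-only peaks (7.16%), ETS for LPS (0.199%) and the ISRE for Pam2CSK4 (16.0%), regions in all 5 lists (23.4%) and regions in 1 list (12.6%), while CTCF newly passed for regions in 1 list (0.744%) and Poly I:C-only peaks (1.35%). The cause was not tested for the changes with other flanks.

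Peak width in place of a score gave the values already reported, since the lists held no score, and was not run again. No paired analysis was possible because 1 list covers both duplicates of a stimulus, and no duplicate was left out for the same reason. The depth behind each list, which limits every count of peaks, was unknown.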

Other observations

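Of 19748 protein-coding genes, 1792 (9.07%) had a RELA peak within 10 kb of a start site under all 5 stimuli, 1296 (6.56%) under 1 stimulus, and 14699 (74.4%) under none. After the 6536 regions held by all 5 lists, and apart from regions in 1 list, the most frequent combinations were LPS with TNFα (829 regions), all stimuli but M tri-DAP (812), all but LPS (637), Pam2CSK4 with Poly I:C (567) and TNFα with Pam2CSK4 (550).

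The innate sensor genes RIGI and IFIH1, chosen after their values were seen, had a RELA peak within 10 kb of a start site under all 5 stimuli. At IFIH1 (hg19, chromosome 2, 163123584 to 163175194, minus strand) the peak over the start site was 1800 bp wide after Pam2CSK4 and 1300 bp after Poly I:C, and 650 bp after TNFα. At IFNB1, the interferon beta gene, also chosen after its values were seen (chromosome 9, 21077103 to 21077941, minus strand), the widest peak lay 7126 to 7261 bp from the start site in each list. The gene IL6, chosen likewise, had a peak over its start site after LPS, TNFα, Poly I:C and M tri-DAP and none within 10 kb after Pam2CSK4.

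Median GC content was 39.6% in LPS-only peaks and 42.9% in TNFα-only peaks, against 46.6% in Pam2CSK4-only, 42.0% in Poly I:C-only and 50.4% in M tri-DAP-only peaks. Their flanks lay between 40.3% and 42.7%. These differences were not tested.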
